A study of Homo sapiens with 8 samples.

How the data were processed

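RNA was measured in 8 libraries of SW480, a human colorectal adenocarcinoma cell line. Per the labels' protocols, the cells were infected with lentivirus and kept under puromycin until a Western blot showed stable overexpression of SPOCK1. RNA was taken in TRIzol, and libraries were made with an Illumina NEBNext Ultra RNA kit. The library titles put 4 libraries in the vector control group and 4 in the SPOCK1 overexpression group, and number them 1 to 4 within each group. The batch label has the same value for every library.

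The values used are whole-number read counts per gene, as deposited, without normalization. CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3 are named in the submitters' processing notes. The genome build, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The table holds 58735 genes. Start, end and strand of all 58735 were identical to those of GENCODE release 29, an annotation of the GRCh38 assembly, and 58708 symbols were identical too. Coordinates are those deposited beside the counts. If reads from several genomic copies were counted for 1 of them or dropped, counts of near-identical genes are uncertain, and without a known strand setting the reads of overlapping genes cannot be separated.

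Total counts lay between 35643585 and 42812951 per library. Counts were compared with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr on the groups, with a minimum count of 10 and a minimum total of 15, which left 15790 genes. Library sizes were scaled with TMM factors, and CPM were computed on the scaled sizes. The quasi-likelihood F test (glmQLFit, glmQLFTest) compared the groups without covariates, and p-values were adjusted by Benjamini-Hochberg over the genes tested. Genes with an adjusted p under 0.05 are called changed. The standard error of a log2 fold change was taken from the F statistic. The ratio of SPOCK1 counts pooled over each group has an exact 95% binomial interval, and a count of 0 was read as allowing up to 3 counts. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

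Before the data were examined, 23 gene lists were fixed, along with the tests, the rule for named genes and most alternatives. Of 739 list symbols, 701 were found under the deposited symbol and 36 through a table of current and older gene names. The other 2 were not found. The 20 lists with at least 5 tested members were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. The rule named SPOCK1, then AXIN2, LGR5, MYC, CCND1, CD44, CTNNB1, PROM1, SOX2, CDH1 and VIM whatever their values. It added the 6 largest rises and 6 largest falls among protein-coding genes past an adjusted p of 0.05, with a mean of at least 1 CPM over all 8 libraries and no overlap between the groups. It also added, for each list past camera, the 3 members with the smallest p among those past 0.05, and for each other list the 1 such member with the smallest p. A gene that 2 parts of the rule named counted under both. The rule named 40 tested genes, not all of which are described in the text.

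Other normalizations (RLE and upper-quartile factors), DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a filter at a mean of 1 CPM, the replicate number as a block, each library left out in turn, and library sizes without SPOCK1 or without mitochondrially encoded genes were the alternatives fixed at that point. Alternatives chosen after seeing the data were per-library offsets on GC content, or on GC content and exonic length, and a block for libraries of higher or lower GC trend. The exact permutation tests of 6 measures per library were also added after seeing the data. For the offsets, each library's log2 CPM deviation from the gene's mean was fitted with natural splines of 5 degrees of freedom. GC content was that of the longest GENCODE transcript and was known for 99.95% of tested genes. Such offsets also remove any biological change that follows GC content or length.

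The tests were tested on simulated data for this comparison, drawn with the means, dispersions and library sizes of these libraries. In these data 200 genes were changed, and a further list of 30 genes was raised by 0.3 on the log2 scale. Calls among those 30 did not count as false. In 15517 simulated genes the quasi-likelihood test recovered 58.2% of the genes changed 1.5-fold, 86.6% of those changed 2-fold and all 66 changed 4-fold, and 3.95% of its calls were false. In the same simulation 13.1% of DESeq2's calls were false. With a GC trend added to every simulated SPOCK1 library and to no control, 95% of calls were false without offsets, in 15480 genes. With offsets on GC content and length 6.67% were false. In the real libraries the trend differed within both groups, so neither rate describes the calls made here. No pair of libraries within a group agreed within sampling noise: the chi-square statistic per degree of freedom was 9.85 or more in every pair. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.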

Results

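Gene expression was profiled by RNA sequencing in SW480, a human colorectal cancer cell line in which the tumour suppressor APC is truncated and Wnt/β-catenin signalling is active. Cells carrying SPOCK1 with a FLAG tag were compared with cells carrying the empty vector, with 4 libraries in each group. SPOCK1, also called testican-1, is a secreted proteoglycan of the extracellular matrix. The series title links it to Wnt/β-catenin signalling and to stemness of colorectal cancer, and the comparison asks which genes differ when it is overexpressed. Libraries held 35643585 to 42812951 counts, of which 2.83% to 3.69% came from mitochondrially encoded genes. Counts of ribosomal RNA genes, mitochondrial ones included, took 0.715% ± 0.017 of the controls and 0.612% ± 0.045 of the SPOCK1 libraries (SD, n = 4 each), without overlap between the groups (exact two-sided permutation p = 0.0286, the smallest this design can give, and 0.171 adjusted over 6 measures per library). This difference runs beside every gene group described for the comparison. Correlations of log2 CPM between libraries were 0.983 to 0.989 within groups and 0.981 to 0.987 between groups. The labels do not say whether the 4 libraries of a group came from separate cultures or separate infections. The p-values therefore measure only the spread between these libraries, which may be technical. If each group is a single selected population, other differences between those populations cannot be told apart from an effect of SPOCK1.

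In SPOCK1-overexpressing cells, 14 of 34 genes of the unfolded protein response were higher and 4 of 25 genes of cholesterol synthesis lower. HSPA5, the main chaperone of the endoplasmic reticulum, rose 1.72-fold, and INSIG1, which holds SREBP transcription factors in the endoplasmic reticulum, fell by 31.5%. CDH1, which encodes E-cadherin, fell by 37.2%, and KREMEN1, a receptor of DKK proteins, fell by 44.4%. AXIN2, a general target of Wnt/β-catenin signalling, and MYC did not pass the test. Errors and p-values of these genes stand with their lists.

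SPOCK1 itself (ENSG00000152377, chromosome 5, 136975298 to 137598379, minus strand) was present at high level in every overexpressing library and nearly absent from every control. It had 6, 0, 3 and 6 counts in control libraries 1 to 4, and 6719, 7828, 9712 and 8964 counts in SPOCK1 libraries 1 to 4. The mean was 220.8 ± 31.1 CPM (SD, n = 4) with the construct and 0.096 ± 0.072 CPM (SD, n = 4) in controls. The control library with 0 counts allows up to 0.081 CPM. Pooled over each group, the ratio of 33223 to 15 counts, scaled to library size, was 2253, with an exact 95% interval of 1366 to 4026 for counting error. With the construct SPOCK1 ranked at place 823 among 15790 tested genes by mean CPM.

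Outside SPOCK1 the changes were small. In SPOCK1-overexpressing cells 39 genes, SPOCK1 among them, rose and 126 fell (edgeR quasi-likelihood test, adjusted p under 0.05). At least 2-fold were 2 of the rises, SPOCK1 and RGPD8, and 15 of the falls. The median change was 1.49-fold among the other rises and 1.535-fold among the falls. Over all genes tested, the groups did not overlap in 8.23%, against an average of 2.86% by chance if the 8 libraries are exchangeable. Genes vary together, so a single split can lie far from that average. The share was not computed for other splits. With tested genes at a mean of at least 1 CPM ordered by GC content into 5 groups of near equal size, 53 of the falls lay in the group with the highest GC content and 5 in that with the lowest. With offsets for GC content and exonic length in each library, 308 genes rose and 286 fell, and 161 of the 165 stayed past the threshold. The GC trend varied between libraries. No difference between the groups passed the test (mean difference of -0.08 on the log2 scale between the highest and lowest GC groups, exact two-sided permutation p = 0.657), but the trend parted libraries 1 and 3 of both groups from libraries 2 and 4. Within libraries 2 and 4 alone, at 2 libraries per group, 140 genes were called, and within libraries 1 and 3 alone 8. All 165 kept their direction in both sets, which was nearly fixed beforehand, since the groups overlapped in none of them. The unfolded protein response list passed camera in both sets (adjusted p = 1.52e-28 and 7.23e-15). The cholesterol list passed downward in both (adjusted p = 6.23e-22 and 3.60e-09), as did the epithelial list and both Wnt lists. Leaving out control library 2, SPOCK1 library 2 or SPOCK1 library 3 left 96, 90 and 89 called genes.

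**Figure D1:**
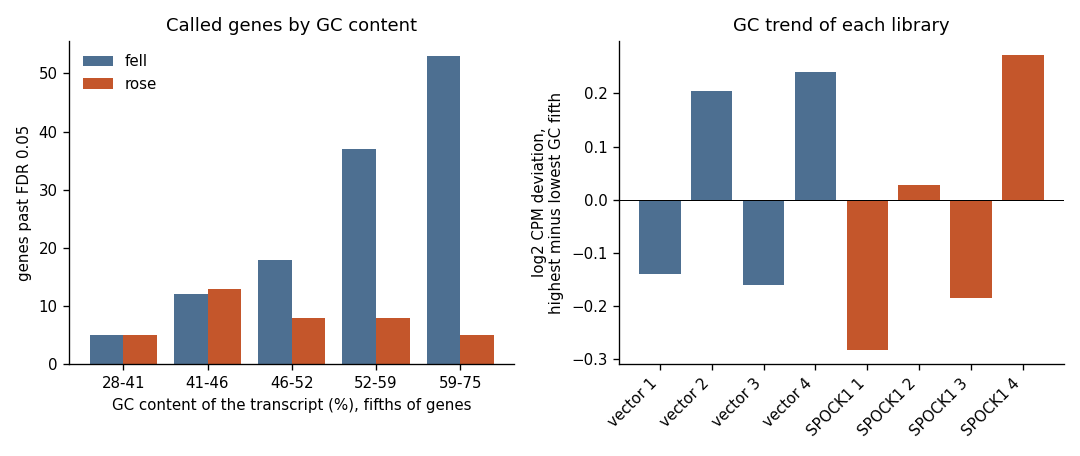
Left, number of genes called as fallen (blue) or risen (orange) in 5 near equal groups of genes at a mean of at least 1 CPM ordered by the GC content of the transcript. Right, for each library, the median deviation of log2 CPM from the gene mean in the highest GC group minus that in the lowest. Falls increase from 5 to 53 with GC content, and libraries 1 and 3 of both groups lie below 0 while libraries 2 and 4 lie above.

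Part of the unfolded protein response list rose. Of 34 tested members, 14 rose, 0 fell and 20 did not pass the test, and adjusted over the list alone 18 rose and 1 fell. Over all genes 16 rose and 1 fell with GC content and length offsets. HSPA5 (chromosome 9, 125234853 to 125241330) rose from 475.7 ± 34.4 to 817.0 ± 36.2 CPM (SD, n = 4 each), a log2 fold change of 0.78 ± 0.08 (SE, adjusted p = 3.42e-05). MANF, a secreted factor of stressed endoplasmic reticulum, rose 1.75-fold (adjusted p = 5.69e-05), and PDIA4, a protein disulfide isomerase, rose 1.61-fold (adjusted p = 6.34e-05). DDIT3, the stress transcription factor CHOP, which overlaps MARS and MBD6, rose from 7.28 ± 1.38 to 12.9 ± 2.07 CPM (adjusted p = 0.0112). Its call was lost without control library 1 or 2, at adjusted p = 0.0522 and 0.0505. XBP1 and ATF4, transcription factors of this response, had log2 fold changes of 0.22 ± 0.08 and 0.15 ± 0.08 and adjusted p of 0.206 and 0.448. Both, like other genes named here outside the naming rule, were chosen after their values were seen. The list passed camera upward (adjusted p = 4.17e-26) and also with an estimated correlation (adjusted p = 3.16e-04).

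Some genes of cholesterol synthesis and uptake fell. Of 25 tested members 4 fell and 0 rose over all genes, 14 fell adjusted over the list alone, and 23 of 25 had a negative log2 fold change, with a median of -0.26. Over all genes 14 fell with GC content and length offsets. INSIG1 (chromosome 7, 155297776 to 155310235) fell from 98.8 ± 4.28 to 67.6 ± 5.72 CPM (SD, n = 4 each), with a log2 fold change of -0.55 ± 0.08 (SE, adjusted p = 0.00204). TM7SF2, a sterol reductase, fell by 31.7% (adjusted p = 0.00133). TM7SF2 overlaps VPS51, so its counts cannot be fully separated from those of its neighbour. The list passed camera downward (adjusted p = 2.93e-17), also with an estimated correlation (adjusted p = 6.83e-04).

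**Figure D2:**
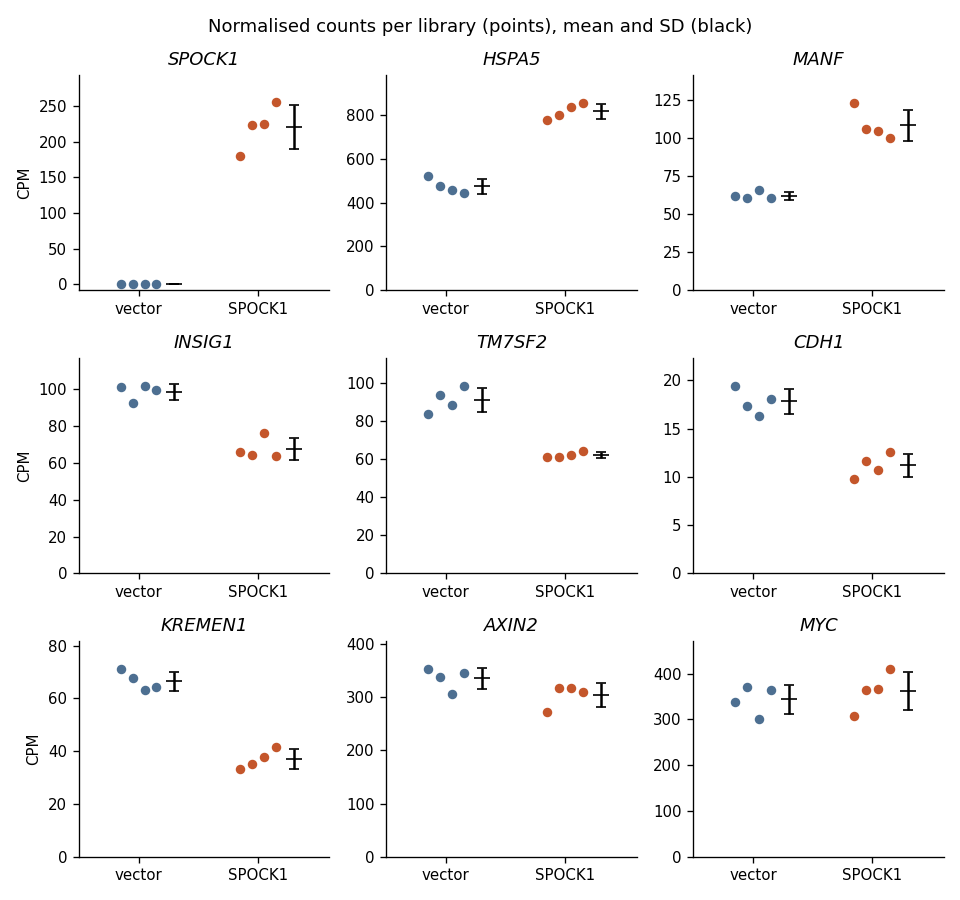
CPM of 9 genes in each library (points), with the mean and SD of each group of 4 libraries in black, for vector control (blue) and SPOCK1 overexpression (orange). HSPA5 and MANF are higher, and INSIG1, TM7SF2, CDH1 and KREMEN1 lower, in every SPOCK1 library than in any control, whereas the groups overlap for AXIN2 and MYC.

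Wnt/β-catenin target genes did not rise as a group. Of 33 tested targets 2 rose, 2 fell and 29 did not pass, and adjusted over the list alone 3 rose and 9 fell. Over all genes 2 rose and 6 fell with GC content and length offsets. CEMIP, a hyaluronan-binding protein that overlaps MESD, fell from 66.8 ± 3.26 to 39.6 ± 7.51 CPM (SD, n = 4 each). Its log2 fold change was -0.75 ± 0.11 (SE, adjusted p = 0.00194). APCDD1, a Wnt inhibitor and target, fell by 23.2% (adjusted p = 0.0102, and 0.0610 without SPOCK1 library 2). FOSL1, an AP-1 transcription factor, rose 1.39-fold (adjusted p = 0.0104), and the Wnt antagonist DKK1, named after its values were seen, had a log2 fold change of 0.75 ± 0.14 (adjusted p = 0.0112). AXIN2, the most general target of the pathway, stood at 335.8 ± 20.5 CPM in controls and 304.4 ± 22.1 with SPOCK1 (log2 fold change -0.14 ± 0.08, adjusted p = 0.446). MYC, CCND1 and CD44 had log2 fold changes of 0.08 ± 0.09, -0.12 ± 0.09 and -0.10 ± 0.08 (adjusted p = 0.761, 0.564 and 0.608). The list leaned downward in camera (adjusted p = 3.55e-04), a call lost with an estimated correlation (adjusted p = 0.498) and by fry (adjusted p = 0.122).

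Among 49 tested components of the Wnt pathway 3 fell and 0 rose, and 4 fell adjusted over the list alone. The list holds Wnt antagonists such as DKK4, so its direction does not give the direction of signalling. The rise of DKK1 was counted among the targets and not here. KREMEN1, a receptor of DKK proteins (chromosome 22, 29073078 to 29168333), fell from 66.5 ± 3.58 to 37.0 ± 3.67 CPM (SD, n = 4 each), with a log2 fold change of -0.85 ± 0.09 (SE, adjusted p = 7.00e-05). DKK4, a Wnt antagonist, fell by 33.8% (adjusted p = 0.00505). DKK3, a DKK family member, fell by 27.6% (adjusted p = 0.0124), and its call was lost without control library 2, SPOCK1 library 2 or SPOCK1 library 3 (adjusted p = 0.0625, 0.0657 and 0.0680). CTNNB1, which encodes β-catenin, had a log2 fold change of 0.14 ± 0.08 (adjusted p = 0.448). The list passed camera downward (adjusted p = 3.55e-04) but not with an estimated correlation (adjusted p = 0.306), and passed fry (adjusted p = 0.0480). With GC content and length offsets 1 component rose and 4 fell over all genes. The rise was AXIN1, a scaffold of the β-catenin destruction complex, at a log2 fold change of 0.21 ± 0.05 (adjusted p = 0.0395), against 0.06 without the offsets.

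Stem cell and tumour-initiating cell markers did not pass the test as a list. Of 22 tested members 1 fell, 0 rose and 21 did not pass, and adjusted over the list alone 1 rose and 1 fell. ABCB1, a drug efflux transporter, fell by 48.3%, from 26.6 ± 3.40 to 13.8 ± 1.54 CPM (SD, n = 4 each, adjusted p = 3.13e-04). It overlaps RUNDC3B. DCLK1, the rise within the list alone, had a log2 fold change of 0.37 ± 0.10 and an adjusted p of 0.111 over all genes. With GC content and length offsets it was called, at 0.44 ± 0.08 (adjusted p = 0.00573). SOX2 stood at 3.26 ± 0.25 CPM in controls and 4.14 ± 0.49 with SPOCK1 (log2 fold change 0.35 ± 0.16, adjusted p = 0.346). The intestinal stem cell receptor LGR5 had 4 counts in all controls together and 4 in all SPOCK1 libraries, and PROM1, which encodes CD133, had 0 in both groups, which allows up to 0.0196 and 0.0199 CPM. The list did not pass camera (adjusted p = 0.261). Its mean log2 fold change was -0.06 and its median 0.0027, so the test's downward sign is that of the mean and not of the median, which lay between -0.10 and 0.02 without 1 library.

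Some epithelial markers fell. Of 28 tested epithelial markers 5 fell and 0 rose, and 9 fell adjusted over the list alone. CDH1 (chromosome 16, 68737225 to 68835548) fell from 17.8 ± 1.29 to 11.2 ± 1.21 CPM (SD, n = 4 each), a fall by 37.2% (log2 fold change -0.67 ± 0.11, SE, adjusted p = 0.00537). CLDN7, a claudin of tight junctions that overlaps ELP5, fell by 29.7% (adjusted p = 0.00528). ELF3, an epithelial transcription factor, fell by 38.2% (adjusted p = 0.0192) and was not called without control library 2 or 4 or SPOCK1 library 2 or 3 (adjusted p = 0.0545, 0.0722, 0.0520 and 0.0803). It overlaps ELF3-AS1. The keratins KRT8, KRT18 and KRT19 and the surface marker EPCAM had log2 fold changes of 0.09, 0.06, 0.15 and 0.01 (SE 0.08 to 0.10), with adjusted p of 0.693, 0.774, 0.454 and 0.981. With GC content and length offsets KRT19 was called as a rise, at 0.21 ± 0.05 (adjusted p = 0.0371), and 7 members fell. The list passed camera downward (adjusted p = 9.45e-06), and with an estimated correlation it had an adjusted p of 0.0797.

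Mesenchymal and EMT markers did not move as a list (adjusted p = 0.448). Of 26 tested members 1 fell and 0 rose, with the same 1 fall adjusted over the list alone. VIM, which encodes vimentin, stood at 227.9 ± 18.5 and 271.6 ± 20.7 CPM (log2 fold change 0.25 ± 0.08, adjusted p = 0.177).

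**Figure D3:**
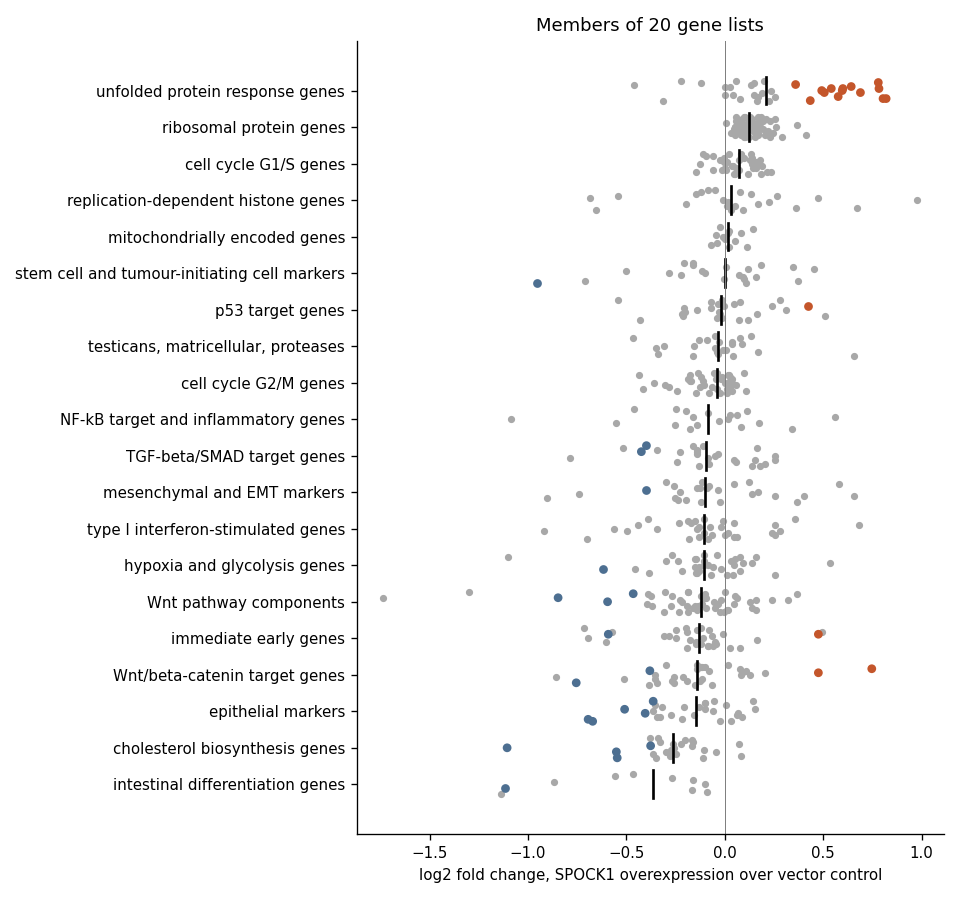
Log2 fold change of each tested member (points) of 20 gene lists, SPOCK1 overexpression over vector control, with list medians as black bars. Orange points rose and blue points fell at an adjusted p under 0.05, and grey points did not pass. The unfolded protein response list holds 14 rises and the cholesterol list 4 falls.

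Intestinal differentiation genes were mostly below the level of testing, with 10 of 40 tested. All 10 had negative log2 fold changes, 1 fell over all genes and 3 fell adjusted over the list alone. CEACAM1, a cell adhesion molecule, fell from 4.25 ± 0.91 to 1.96 ± 0.18 CPM (SD, n = 4 each, adjusted p = 0.00640). It overlaps LIPE-AS1. The list passed camera (adjusted p = 9.82e-05), and with an estimated correlation the adjusted p was 0.0797. With no filter beyond 1 count it was 0.0553.

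A further 4 lists passed camera with small shifts. Ribosomal protein genes had 63 of 63 positive log2 fold changes with a median of 0.12, which was 0.07 without control library 1 or SPOCK1 library 1, and 0 were called, neither over all genes nor adjusted over the list alone. Camera gave an adjusted p of 3.70e-08, and 0.545 with an estimated correlation, and fry gave 0.325. G1/S genes had a median of 0.07, which was 0.03 without SPOCK1 library 1 and 0.05 without control library 4, with 0 of 39 called by either adjustment (adjusted p = 0.0196, and 0.215 with an estimated correlation). That call was lost with GC content and length offsets (adjusted p = 0.075) and without control library 4 (adjusted p = 0.0522). Hypoxia and glycolysis genes leaned downward (adjusted p = 0.0219, and 0.306 with an estimated correlation). Of their 35 tested members ALDOC, an aldolase, was the 1 that fell, by 34.9% (adjusted p = 0.0271), with 4 falls adjusted over the list alone and 3 over all genes with GC content and length offsets. Its call was lost with the replicate number as a block (adjusted p = 0.0557) and in 7 of 8 fits without a library, control library 4 being the exception, with adjusted p of 0.0543 to 0.0766. The list's own call was lost with GC content and length offsets (adjusted p = 0.075) and without control library 2 or 4 or SPOCK1 library 3 (adjusted p = 0.102, 0.0558 and 0.109). Immediate early genes leaned downward (adjusted p = 0.0115, and 0.545 with an estimated correlation), a call lost by fry (adjusted p = 0.246) and without control library 2 or 4 or SPOCK1 library 1 (adjusted p = 0.0645, 0.0522 and 0.275). Of 32 tested members FOSL1 rose and NR4A1, an orphan nuclear receptor, fell by 33.6% (adjusted p = 0.0112, and 0.0515 without control library 2). Adjusted over the list alone 1 rose and 3 fell, and with GC content and length offsets 2 rose and 4 fell over all genes.

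The other lists did not pass camera. BHLHE40, a transcription factor, fell by 25.4% (adjusted p = 0.0180) as 1 of 2 falls among 26 tested TGF-β/SMAD targets, where adjusted over the list alone 1 rose and 2 fell (list adjusted p = 0.141). The BHLHE40 call was lost with the replicate number as a block (adjusted p = 0.0514) and without control library 1 or 2 or SPOCK1 library 2 or 3 (adjusted p = 0.0594, 0.0640, 0.0755 and 0.0673). The list itself passed without control library 3 or SPOCK1 library 4 (adjusted p = 0.0448 and 0.0263). PLK2, a stress-induced kinase, rose 1.34-fold (adjusted p = 0.0464) as the 1 call among 26 p53 targets, with 1 rise and 1 fall adjusted over the list alone (list adjusted p = 0.867). Its call was lost with the replicate block (adjusted p = 0.0527) and in 6 of 8 fits without a library, those without control library 1 or SPOCK1 library 4 being the exceptions, with adjusted p of up to 0.184. The p53 list had an upward test beside a mean of 0.00 and a median of -0.02. Testicans and matrix genes (0.460), G2/M genes (0.197), interferon-stimulated genes (0.169), NF-kB targets (0.328), mitochondrially encoded genes (0.606) and histone genes (0.369) held no call over all genes, with their list's adjusted p in parentheses. Adjusted over the list alone, 1 NF-kB target fell and no member of the other 5 was called. G2/M genes passed downward with offsets on GC content (adjusted p = 0.0436) and without SPOCK1 library 1 (adjusted p = 0.0198). They also passed downward with offsets on GC content and length (adjusted p = 0.00304, and 0.0407 with an estimated correlation as well). Interferon-stimulated genes passed downward by fry (adjusted p = 0.0264). Among TGF-β/SMAD targets 1 rose and 2 fell with GC content and length offsets, and among p53 targets 1 rose and 2 fell. In lists without a call, GC content and length offsets gave rises of GPC1 among testicans and matrix genes and RFC2 among G1/S genes (adjusted p = 0.0231 and 0.0293), and falls of KIF20A among G2/M genes and IFITM1 among interferon-stimulated genes (adjusted p = 0.0441 and 0.0103). Markers of fibroblasts, leukocytes and endothelium had 3, 1 and 3 tested members, too few for the list test, and none was called.

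Other genes named for the size of their change lay at low to moderate level. PARM1, a mucin-like membrane protein, fell by 64.3%, from 8.85 ± 0.74 to 3.16 ± 0.54 CPM (SD, n = 4 each), with a log2 fold change of -1.49 ± 0.15 (SE, adjusted p = 5.24e-05). NXPH3, a neurexophilin, fell by 57.5% (adjusted p = 3.12e-04), and ADGRB1, an adhesion G protein-coupled receptor, had a log2 fold change of -1.15 ± 0.16 (adjusted p = 0.00126). SEMA4G, a semaphorin that overlaps MRPL43, fell by 54.7% (adjusted p = 0.0180). Its call was lost with the replicate block (adjusted p = 0.0720) and without control library 1 or 2 or SPOCK1 library 2 or 3 (adjusted p = 0.0519, 0.0702, 0.0655 and 0.0531). CD8B fell by 58.6%, from 19.4 ± 1.39 to 8.03 ± 0.95 CPM (adjusted p = 2.20e-05), and its near-identical paralog CD8B2, at 220.5 CPM in controls, fell too (log2 fold change -0.44 ± 0.08, adjusted p = 0.0137), so reads may be shared between them. DBH, dopamine beta-hydroxylase, fell by 54.6% (adjusted p = 1.21e-04) and its overlapping antisense transcript DBH-AS1 had a log2 fold change of -1.09 ± 0.13 (adjusted p = 1.80e-04), and without a known strand setting the counts of the pair cannot be separated. Among the rises, FAM129A rose 1.81-fold (adjusted p = 0.00233), and NT5E, the ecto-enzyme CD73, rose 1.79-fold from 2.56 ± 0.27 CPM (adjusted p = 0.0140, and 0.0519 without control library 1). RGPD8 rose from 0.54 ± 0.26 to 1.95 ± 0.77 CPM (adjusted p = 0.0174). Its call was lost with the replicate block (adjusted p = 0.0820) and without control library 2 or 4 or SPOCK1 library 2 (adjusted p = 0.0660, 0.0508 and 0.0945). Its near-identical copies RGPD5, RGPD3 and RGPD6 had log2 fold changes of -1.55 ± 0.39, -1.001 ± 0.306 and -0.77 ± 0.49 (adjusted p = 0.0718, 0.151 and 0.511), so how reads were assigned among the copies may decide its value.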

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

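The offsets on GC content and exonic length, the fits on libraries grouped by GC trend, and the decision to weigh the share of falls were chosen after the results were seen, while the bounds on the offset tests were written before those tests were run. The comparison with splits balanced over the GC trend and the counts of splits for single lists were chosen after the splits had been counted for genes and lists past the test.

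Of 92 groups of 4 values examined for a library far from the others, 5 had such a library, against 4.6 from chance. AXIN2 was low in SPOCK1 library 1 (gap over range 0.834), at 8.09 log2 CPM against 8.28 to 8.31 in the other 3. CD44 was low in control library 3 (gap over range 0.852), at 7.38 log2 CPM against 7.57 to 7.60. Total counts were high in control library 4 (gap over range 0.838), at 41343049 against 36390186 to 37191599. The number of genes with a count was low in control library 2 (gap over range 0.903). That number was high in SPOCK1 library 3 (gap over range 0.929).

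The rise of unfolded protein response genes had a median log2 fold change of 0.60 over its 14 called members. With GC content and length offsets that median was 0.61, all 14 stayed called and the median of all 34 members went from 0.21 to 0.22, which argues against a GC or length trend. Without 1 library the lowest median of the 14, which were picked for the pattern, was 0.57, and that of all 34 members lay between 0.20 and 0.25, which argues against a single library. Of 35 splits of the 8 libraries into 4 and 4, only the real one (1 split) gave a camera p as small. It was 2.09e-27, against 3.21e-09 for the next. This argues against chance only as far as the 8 libraries are exchangeable, which the GC trend puts in doubt. A response to the making of any secreted protein in excess, apart from what SPOCK1 itself does, stays open and untested as a hypothesis, since no other secreted protein was overexpressed for comparison.

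More genes fell than rose, at 76.4% of 165. With offsets on GC content and length 48.15% of 594 fell, which met the bound written beforehand for such a trend as the cause. That bound was set aside, since 122 of the 126 falls stayed called while rises went from 39 to 308. The offsets also centre each GC and length range, so whether a GC and length trend made the excess stays open. RLE and upper-quartile factors gave at least 74.85% falls, which met the bound written beforehand against the scaling factors as the cause. That bound was set aside too, since these factors moved the median log2 fold change of all genes only from -0.0042 to 0.00049 and 0.0011. The choice of scaling factors therefore stays open as well. For the count of genes itself, the real split was the only 1 of 35 with as many, 165 against at most 145. It was also the only 1 of 35 with as many at least 2-fold, 17 against 5. Both argue against chance only as far as the 8 libraries are exchangeable. The split with 145 genes exchanges control library 3 and SPOCK1 library 4, and the split of libraries 1 and 3 against 2 and 4 called 90, which points to a structure of the samples beside the groups.

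The Wnt target and Wnt component lists leaned downward, each at adjusted p = 3.55e-04. With an estimated correlation the adjusted p was 0.498 for the targets and 0.306 for the components. With GC content and length offsets the higher of their camera adjusted p was 0.00328, which met the bound written beforehand against such a trend. With an estimated correlation as well it was 0.405 for the targets and 0.313 for the components. Neither list passed with an estimated correlation without offsets either, so those values cannot decide for or against the trend. The components' median log2 fold change went from -0.12 to -0.05 (targets -0.14 to -0.12). Without SPOCK1 library 1 the medians were -0.07 and -0.09, so a contribution of the trend stays open for the components. Chance is not excluded for either list: 6 of 35 splits gave a camera p as small for the targets (1.24e-04, against 8.43e-07 for the smallest other) and 2 of 35 for the components (1.11e-04, against 6.12e-05). The lean of both lists may therefore be a property of how these 8 libraries vary, and no biological explanation was tested.

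For the count of lists past camera chance is not excluded either, since 7 of 35 splits gave as many as 10 and the highest other gave 12. Among single lists, only the real split gave a camera p as small for cholesterol synthesis (1 of 35, 2.93e-18 against 1.16e-09) and epithelial markers (1 of 35, 1.89e-06 against 3.14e-04). Here too this argues against chance only as far as the libraries are exchangeable. With an estimated correlation the adjusted p was 6.83e-04 for the first and 0.0797 for the second. For ribosomal protein genes chance is not excluded, with 16 of 35 splits as small (5.55e-09, against 9.42e-28).

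The 35 splits treat the 8 libraries as exchangeable, which the GC trend that parts libraries 1 and 3 from 2 and 4 puts in doubt. Only 18 splits take 2 libraries of each kind into each group, as the real one does, too few for a share under 0.05. Among these 18 the real split called 165 genes and the highest other 1, and at least 2-fold 17 against 1. The smallest camera p of the others was 3.21e-09 for the unfolded protein response, 1.16e-09 for cholesterol synthesis and 5.82e-04 for epithelial markers.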

How the results depend on the processing

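The GC content and length offsets, alone or with an estimated correlation, and the block for GC trend were chosen after the data were seen. Where no cause is named below, the cause was not tested. The count of 165 genes was 398 with DESeq2, whose calls were 13.1% false on simulated data, 399 with no filter beyond 1 count, 376 with GC offsets, 594 with GC content and length offsets and 351 with the GC trend as a block. It ranged from 89 to 237 without 1 library. The count of 17 genes at least 2-fold was 35 with DESeq2 and 55 without the filter, and 13 to 24 without 1 library. With the replicate number as a block the counts were 115 and 12. Correlations of deviations between equal numbers were -0.159, 0.0902, 0.113 and 0.176, too low to show that equal numbers pair the libraries. These correlations do not show that the numbers carry no shared structure, since the GC trend parted odd from even numbers in both groups. The SPOCK1 log2 fold change stayed between 10.71 and 11.48 in all 19 alternatives.

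The count of 10 lists was 2 with an estimated correlation and 5 with that and GC content and length offsets, and 7 to 11 without 1 library. Under those 2 alternatives the adjusted p of Wnt components was 0.306 and 0.313 (range over alternatives 7.74e-05 to 0.313), and that of Wnt targets 0.498 and 0.405, and 0.122 by fry (range 1.03e-05 to 0.498). Unfolded protein response and cholesterol lists passed under all 22 alternatives. The stem cell list passed under none of 22.

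In 5 lists that did not pass, the direction reversed under an alternative, without a call. Adjusted p of mitochondrially encoded genes (range 0.0558 to 0.912) was then 0.822 with GC offsets, 0.0645 with GC content and length offsets, 0.668 with these and an estimated correlation, and 0.715, 0.912 and 0.439 without control library 1, control library 2 and SPOCK1 library 4. For p53 targets (range 0.712 to 0.994, and 0.712 to 0.9486 without 1 library) it was 0.931 with GC content and length offsets, 0.929 with an estimated correlation as well, 0.869 by fry and 0.845 without SPOCK1 library 1. For histone genes (range 0.127 to 0.823) it was 0.5565 and 0.611, and for testicans (range 0.08405 to 0.929) 0.911 and 0.929, with the offsets and with an estimated correlation as well. For mesenchymal markers (range 0.0824 to 0.8545) it was 0.845 without SPOCK1 library 1. Of 33 called named genes 21 passed under all 20 alternatives and 12 lost the call under at least 1. None of the 40 changed direction. LGR5 with 4 counts per group and PROM1 with 0 did not pass the filter and were not tested.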

Other observations

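The comparison of parts of the unfolded protein response list and the GC trend per library were chosen after the values were seen.

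Within the unfolded protein response list, 13 of 18 folding and degradation genes of the endoplasmic reticulum rose, with a median log2 fold change of 0.52, and 1 of 11 targets of the stress transcription factor ATF4 rose, DDIT3, with a median of 0.04. The medians differed by 0.48. Because the parts were defined from these values, the same libraries cannot test the difference.

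Libraries 1 and 3 of both groups had GC trends of -0.14, -0.16, -0.28 and -0.18, and libraries 2 and 4 of both groups had 0.21, 0.24, 0.03 and 0.27, while the batch label is the same for all 8.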
